A study of Macaca mulatta with 20 samples.

How the data were processed

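Total RNA of 20 rhesus macaque corpora lutea, 20 biological replicates per the series design, was hybridised to Affymetrix rhesus genome arrays, 1 array per corpus luteum. Per the labels' protocols, RNA was extracted with Trizol and cleaned on RNeasy columns, and 2 µg went into 1 cycle of labelling with biotin. The authors made the deposited values with RMA, per the submitters' processing notes, and they are on a log2 scale, 1 value per probe set and array. The version of RMA, the chip definition and any filter are not stated. The log2 unit was read from the values, which run from 2.48 to 14.28. They were used as they stand, with no further scaling.

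Of 52865 probe sets, 158 array controls were left out and 52707 tested, with no filter on dim probe sets. Gene symbols came from the platform's annotation: 24956 probe sets had 1 symbol, 361 had several and 27390 had none. The 24956 covered 14132 genes, 6375 of them with more than 1 probe set, and each gene was represented by its probe set with the highest mean over the 20 arrays. Names came from gene identifiers, of which 340 matched no gene of the current table. No genome or probe sequence was used.

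The stage of each array was taken from its title. In R 4.3.3, limma 3.58.1 fitted the mean of each of the 5 stages to all 20 arrays, with 15 residual degrees of freedom and 2.75 prior degrees of freedom, and tested any difference between stages and 7 comparisons. These were each later stage against the early stage, and mid-late against mid, late against mid-late and very-late against late. All tests were two-sided. Benjamini-Hochberg adjustment ran over the 52707 probe sets in each comparison, and an adjusted p under 0.05 counts as past the test. For arrays, their number limits the precision. The lowest p that an exact permutation of 4 against 4 arrays can give is 0.0286, so comparisons of single quality measures, 14 of them, used exact two-sided permutation tests over 70 permutations. The smallest p among them was 0.0286, the smallest possible, and the smallest adjusted p was 0.2.

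The comparisons, tests, alternatives, 33 gene lists and the rule for named genes were fixed before the data were examined. The lists hold 574 members, of which 407 were measured. They were tested on the 14132 genes with limma's camera at a preset correlation of 0.01, adjusted over the 231 pairs of list and comparison, and again with an estimated correlation and with fry. The preset correlation called 46 of the 231, the estimated correlation 0 (smallest adjusted p = 0.161). With fry 45 were called, but these were not all the same pairs: 34 of the 46 were kept, 12 lost and 11 added. Counts of members are given over all probe sets and adjusted over the list alone. Named genes were, in each comparison, the 6 largest rises and the 6 largest falls past the test, at least 2-fold, with the 4 arrays of one stage all on one side of the other 4; up to 4 members of each list past the same threshold; and 21 fixed genes whatever their result. Of the 21, 14 had a probe set with their symbol alone. The others have no value here. The text names only some of the genes that the rule takes.

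The procedure was tested on simulated data. In mid against early, 50 probe sets per size were given a true change, and 68% of those at 1.5-fold, 90% at 2-fold, 94% at 4-fold and 100% at 8-fold were called, with 9 false calls (4.87% of calls). In very-late against late the shares were 76%, 90%, 96% and 100%, with 8 false calls (4.23%). With no true change there were 0 calls in limma. A list of 13 members shifted by 1.5-fold was called with both correlations, and 0 of 32 unshifted lists were. The simulated probe sets varied independently of each other, with the same spread in all stages. They could therefore not show how correlation between list members affects the list tests.

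The alternatives were leaving out dim probe sets, cyclic loess scaling, median centring, a trended and robust prior, array weights, the replicate number as a block, 1 probe set per gene, a minimum of 2-fold, an adjusted p under 0.01, the mean of a gene's probe sets, fits on the 8 arrays of the 2 stages compared, and leaving out each array in turn. Added after seeing the data were fits with a term for a split of the arrays by mitochondrial probe sets, on the 13 arrays of its high group, and without very-late replicates 1 and 2 or all very-late arrays.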

Results

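RNA of 20 rhesus macaque corpora lutea was measured on Affymetrix arrays, 1 array per corpus luteum. The corpus luteum is the gland that forms from the ovulated follicle and secretes progesterone. It was collected at 5 stages of natural menstrual cycles, counted in days after the surge of luteinizing hormone: early (days 3 to 5), mid (days 7 to 8), mid-late (days 10 to 12), late (days 14 to 16) and very-late (days 18 to 19), with 4 arrays each. Per the labels, luteal tissue forms at the early stage, progesterone output peaks at the mid stage and is still high at mid-late, secretion ends at the late stage, and the tissue breaks down at the very-late stage. The deposited values ran from 2.48 to 14.28 on a log2 scale, with array medians of 3.88 to 3.98. Arrays of the same stage correlated across probe sets at r = 0.964 to 0.996 and arrays of different stages at r = 0.906 to 0.994. Probe sets are not independent replicates. The first principal component held 46.6% of the variance and the second 14.26%. For arrays, their number limits the precision.

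Some arrays stood apart in ways the stages do not name. In very-late replicate 1 the GAPDH signal at the 3' end exceeded the 5' end by 2.70 log2 units. The other 19 arrays lay at 0.831 to 1.78. This is 1 measure of RNA quality. By the same measure on actin the array was at 0.117, inside the range of the other 19 (-0.199 to 0.973). The GAPDH and actin measures disagree, so degradation of its RNA is not shown. Very-late replicate 2 had the lowest correlation with the mean of its own stage, r = 0.973. On average over 4 probe sets of the mitochondrial genome, 7 arrays lay at 6.07 to 8.50 and the other 13 at 12.6 to 13.6. The 7 were all 4 mid arrays with early replicate 4, mid-late replicate 1 and very-late replicate 2.

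Across the 5 stages, STAR, HSD3B2 and CYP19A1, genes of steroid synthesis, had their lowest means at the very-late stage, while CD68, a marker of macrophages, had its highest mean there. STAR, which carries cholesterol into the mitochondrion, was at 13.19 ± 0.15 (log2, SD, n = 4) at the early stage, 13.36 ± 0.06 at the late stage and 9.15 ± 1.26 at the very-late stage. HSD3B2, which makes progesterone from pregnenolone, went from 12.00 ± 0.13 at the early stage to 9.35 ± 1.14 at the late and 6.05 ± 0.41 at the very-late stage. CYP19A1, the aromatase that makes estrogens, was lower at the early stage (9.23 ± 0.55) than at the mid stage (11.19 ± 0.85) and fell to 6.24 ± 0.70 at the very-late stage. CD68 was at 7.59 ± 0.07 at the early stage and 10.90 ± 0.42 at the very-late stage. TOP2A, a topoisomerase of dividing cells, went from 8.05 ± 0.46 to 5.17 ± 0.48. In limma's test for any difference between stages, 11 of the 14 measured genes of the fixed list passed: STAR, HSD3B2, CYP19A1, CD68, TOP2A, MKI67, INHA, TIMP1, COL1A1, ABCA1 and PGR. ABCA1 and PGR stayed near the low end of the scale, at means of 3.62 to 4.05 and 3.26 to 3.86. The PGR means at the late (3.30) and very-late stage (3.26) lay below 3.42, the median of the viral-genome probe sets, taken as background. PGR was thus not above background there. CYP17A1 (adjusted p = 0.427), MMP2 (adjusted p = 0.163) and PECAM1 (adjusted p = 0.292) did not pass. Over all 52707 probe sets, 11311 (21.5%) passed, 4249 of them with at least a 2-fold range.

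**Figure D1:**
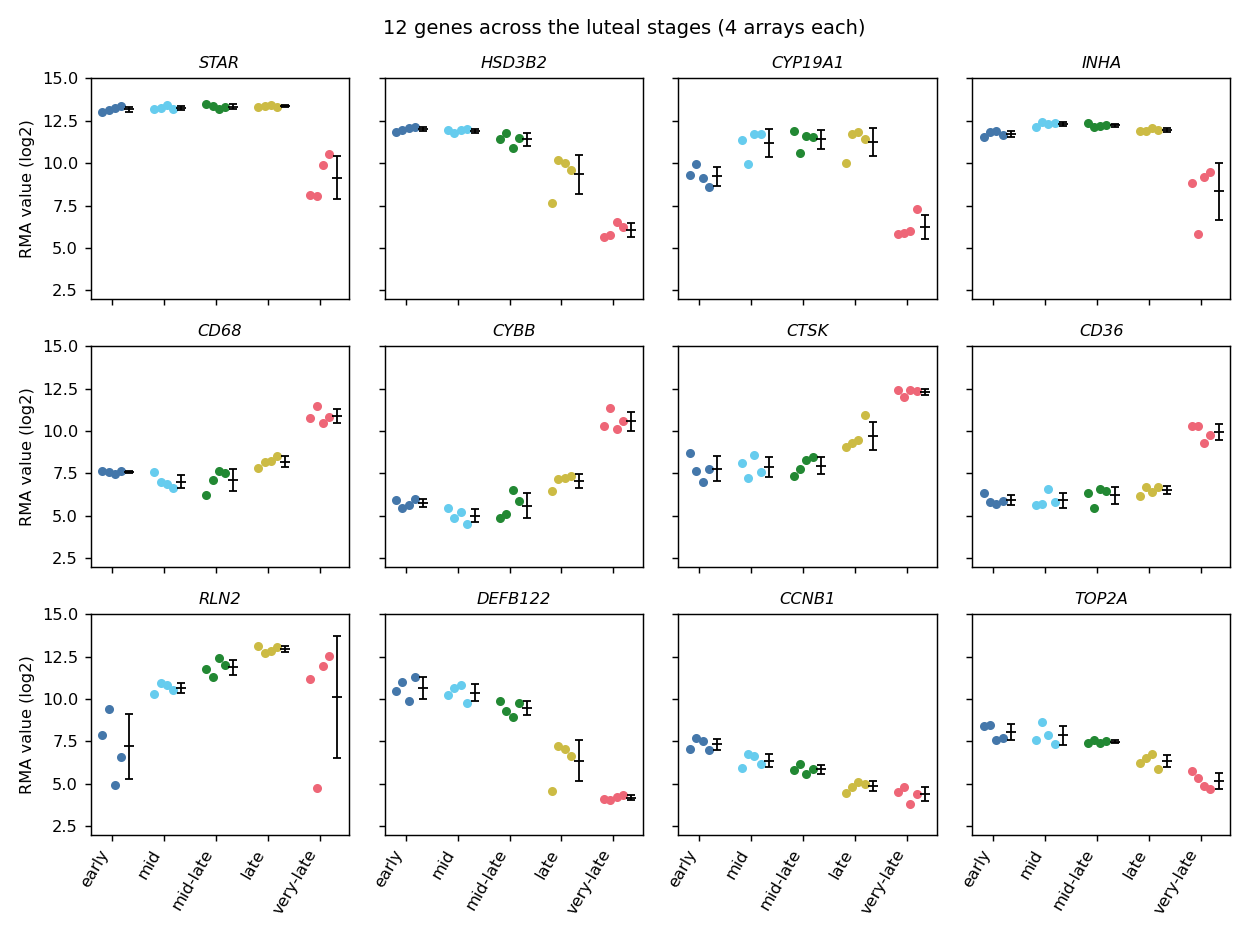
RMA values (log2) of 12 genes on each array, by stage, with arrays 1 to 4 from left to right and the mean with its SD (n = 4) as a black bar. STAR lies between 13.03 and 13.51 on the 16 arrays of the first 4 stages and between 8.05 and 10.6 on the 4 very-late arrays.

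**Figure D2:**
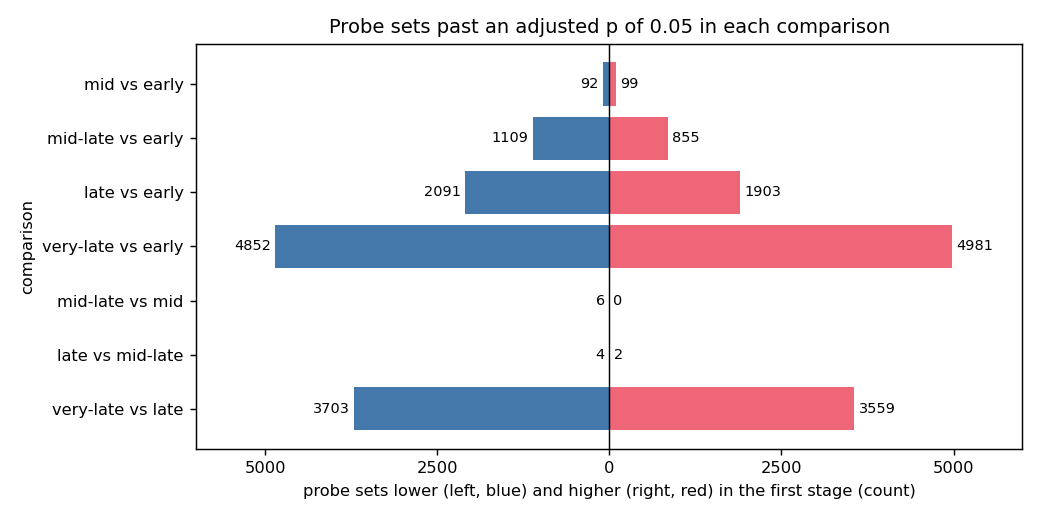
Number of probe sets past an adjusted p of 0.05 in each comparison, lower in the first-named stage to the left and higher to the right. The counts grow from 92 lower and 99 higher between mid and early to 4852 and 4981 between very-late and early.

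Each change below is a difference of log2 stage means ± its standard error in the limma fit, with n = 4 arrays per stage. That error uses 1 spread per probe set over all 5 stages, so it can differ from the SDs of the 2 stages compared. For STAR it was 0.38 in each comparison, while the SD was 0.06 to 0.15 at the first 4 stages and 1.26 at very-late. For each named gene the 4 arrays of one stage lay on one side of all 4 of the other, unless the text says otherwise. Values are those of the representative probe set, and other probe sets of a gene did not always pass. In very-late against late, 1 of 2 passed for CD68, SOD2 and COL1A1, 1 of 3 for TIMP1 and ATF3, and 2 of 6 for BCL2L11. For CTSS all 4 passed and for HPGD all 5.

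The comparison of the mid with the early stage asks what changes as the tissue matures. F3, the tissue factor that starts blood clotting, fell by 2.53 ± 0.35 (adjusted p = 0.00582). AQP11, a water channel, fell by 1.54 ± 0.20 (adjusted p = 0.00410), and PTX3, a secreted pentraxin of the matrix around the oocyte, fell by 2.32 ± 0.45 (adjusted p = 0.0354). TMPRSS7, a serine protease, fell by 2.31 ± 0.41 (adjusted p = 0.0270), to a mean of 3.52 that lay within its SD of background, the median of 3.42 of the viral-genome probe sets. LCAT, which esterifies cholesterol in plasma lipoproteins, rose by 1.42 ± 0.22 (adjusted p = 0.0140). HBB, the beta chain of haemoglobin, rose by 1.44 ± 0.26 (adjusted p = 0.0270). CYP19A1 was higher by 1.96 ± 0.47 and did not pass (adjusted p = 0.0737).

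The list of cell proliferation genes was called lower at the mid stage (adjusted p = 3.06e-10). With an estimated correlation between members the adjusted p = 0.183. Of its 17 measured members 1 fell over all probe sets and 14 fell adjusted over the list alone. The 1 was MCM5, part of the helicase that opens DNA for replication, chosen after its value was seen (-0.55 ± 0.12, adjusted p = 0.0474). The erythrocyte markers were called higher (adjusted p = 0.00179, and adjusted p = 0.183 with an estimated correlation), with 1 of 5 members (HBB) past the test over all probe sets and 3 adjusted over the list alone. Monocyte and macrophage markers were called lower (adjusted p = 0.00244, and adjusted p = 0.579 with an estimated correlation). None of their 16 members passed limma's test over all probe sets, 5 were lower adjusted over the list alone, and at an unadjusted p under 0.05 7 were lower and 1 higher. Complement genes were called lower (adjusted p = 0.0195, and adjusted p = 0.380 with an estimated correlation) with 0 of 12 members past limma's test, 1 adjusted over the list alone, and 3 lower at an unadjusted p under 0.05. The hormone receptors were called higher (adjusted p = 0.0214, and adjusted p = 0.298 with an estimated correlation) with 0 of 10 past limma's test, 3 adjusted over the list alone and 3 higher at an unadjusted p under 0.05.

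Over all probe sets 99 were higher and 92 lower at the mid stage, 63 of them by at least 2-fold. With cyclic loess scaling 87 were higher and 95 lower, and with median centring 83 and 85, so this balance depends on the scaling. The groups did not overlap for 6.24% of probe sets, where chance gives 2.86%. The 191 calls became 53 without early replicate 3, 30 without mid replicate 3, 59 without mid replicate 4, and 19 with a term for the 2 mitochondrial groups of arrays, an alternative chosen after seeing the data. That term overlaps with stage, since all 4 mid arrays and only 1 of the 4 early arrays are low. The 191 became 25 on the 8 arrays of the 2 stages, 324 without dim probe sets, 534 with array weights, and 614 without very-late replicates 1 and 2 and 593 without all very-late arrays, the last 2 chosen after seeing the data. F3, AQP11 and LCAT passed in every fit that left out 1 array. PTX3 did not pass without mid replicate 1, 2 or 3 (adjusted p = 0.0527 to 0.113). TMPRSS7 failed without mid replicate 3 or 4 (adjusted p = 0.0908 and 0.0679). HBB failed without early replicate 1 or 3 or mid replicate 3 or 4 (adjusted p = 0.0502 to 0.0974). MCM5 failed without early replicates 2, 3 or 4 or mid replicate 3 or 4 (adjusted p = 0.0534 to 0.156). The other 6 of the 12 largest changes failed without early replicate 3 (adjusted p = 0.0687 to 0.131) and without mid replicate 3 (adjusted p = 0.0908 to 0.123). Of these 6, 5 failed without early replicate 4, mid replicate 2 or mid replicate 4 (adjusted p up to 0.0819, 0.0714 and 0.110), and 3 without early replicate 1 (up to 0.0703). PTX3 was at -1.71 without early replicate 4. CYP19A1 passed without mid replicate 2 (2.38, adjusted p = 0.0308, against 0.0507 to 0.218 over its other fits).

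The comparison of the mid-late with the early stage spans the time from luteal formation to the end of full function. HTR2B, a serotonin receptor, rose by 3.36 ± 0.48 (adjusted p = 0.00158). ECHDC2, a mitochondrial protein of the enoyl-CoA hydratase family, rose by 3.05 ± 0.47 (adjusted p = 0.00234), and CRYZ, a quinone reductase, rose by 2.89 ± 0.44 (adjusted p = 0.00211). RLN2, the hormone relaxin, rose by 4.67 ± 1.20 (adjusted p = 0.0371), and SERPINA4, the protease inhibitor kallistatin, rose by 3.99 ± 0.91 (adjusted p = 0.0194). CYP19A1 rose by 2.18 ± 0.47 (adjusted p = 0.0138). F3 fell by 2.84 ± 0.35 (adjusted p = 0.000746). The vesicle transport gene MLPH fell by 2.53 ± 0.36 (adjusted p = 0.00158), the beta-defensin DEFB119 fell by 2.44 ± 0.32 (adjusted p = 0.000992). PTX3 fell by 2.41 ± 0.45 (adjusted p = 0.00645), and ENPP3, an ectoenzyme that splits nucleotides, fell by 2.38 ± 0.42 (adjusted p = 0.00490).

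Some members of fixed lists passed while their lists were not called. KDR, a receptor for vascular endothelial growth factor, rose by 1.31 ± 0.25 (adjusted p = 0.00796), and ZFP36, which promotes mRNA decay, rose by 1.68 ± 0.32 (adjusted p = 0.00675). FSTL3, which binds activin, fell by 1.79 ± 0.21 (adjusted p = 0.000614). IGFBP4, which binds insulin-like growth factors, fell by 1.05 ± 0.19 (adjusted p = 0.00510). COL6A3, a chain of collagen VI, fell by 1.15 ± 0.25 (adjusted p = 0.0138). Of the 17 cell proliferation genes 9 fell over all probe sets and 15 adjusted over the list alone, and the list was called lower (adjusted p = 7.72e-10, and adjusted p = 0.183 with an estimated correlation). CCNB1, the cyclin of entry into mitosis, fell by 1.46 ± 0.23 (adjusted p = 0.00238), while the proliferation marker MKI67 was at -0.91 ± 0.26 and did not pass (adjusted p = 0.0581). Endothelial cell markers were called higher (adjusted p = 0.0266, and adjusted p = 0.861 with an estimated correlation). Of their 13 members 1 rose over all probe sets and 1 adjusted over the list alone: EMCN, a surface protein of endothelial cells, chosen after its value was seen (0.98 ± 0.23, adjusted p = 0.0257). Another probe set of EMCN differed between the high and the low mitochondrial group, by 1.64 ± 0.20 within stages. Only the early, mid-late and very-late stages held arrays of both groups. The probe set reported here was not among those called for that split.

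Over all probe sets 855 were higher and 1109 lower at the mid-late stage, 400 by at least 2-fold, and the groups did not overlap for 11.9% of probe sets (2.86% by chance). The 1964 calls became 1016 without early replicate 3, 1228 without early replicate 4, and 1132, 806 and 1079 without mid-late replicates 1, 3 and 4. They became 3758 with array weights, and 3231 without very-late replicates 1 and 2 and 3197 without all very-late arrays, the last 2 chosen after seeing the data. RLN2 passed only without early replicate 2 among the fits that left out 1 of the 8 arrays (adjusted p = 0.0523 to 0.132 in the other 7). SERPINA4 failed without early replicates 3 or 4 or mid-late replicates 3 or 4 (adjusted p = 0.0532 to 0.0736). CYP19A1 failed without mid-late replicate 3 (adjusted p = 0.0503). EMCN failed without early replicates 3 or 4 or any mid-late replicate (adjusted p = 0.0514 to 0.0795). RLN2 was at 5.41 without early replicate 2 and 3.91 without early replicate 3, SERPINA4 at 4.95 without early replicate 2, PTX3 at -1.80 without early replicate 4 and ENPP3 at -3.01 without early replicate 3. The mid-late mean of PTX3, 3.904, lay within its SD of background.

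The comparison of the late with the early stage asks what has changed by the time progesterone secretion ends. HSD3B2 fell by 2.65 ± 0.37 (adjusted p = 0.000324), and HSD11B1, which interconverts cortisone and cortisol, fell by 2.27 ± 0.32 (adjusted p = 0.000293), while CYP19A1 rose by 2.03 ± 0.47 (adjusted p = 0.0110). RLN2 rose by 5.75 ± 1.20 (adjusted p = 0.00606), SERPINA4 by 5.14 ± 0.91 (adjusted p = 0.00182). ECHDC2 rose by 3.30 ± 0.47 (adjusted p = 0.000375), HTR2B by 3.30 ± 0.48 (adjusted p = 0.000401) and CHIT1, a chitinase of macrophages, by 3.28 ± 0.56 (adjusted p = 0.00153). The beta-defensins DEFB122 and DEFB119 fell by 4.29 ± 0.44 (adjusted p = 2.44e-05) and by 4.04 ± 0.32 (adjusted p = 5.29e-06). F3 fell by 3.73 ± 0.35 (adjusted p = 1.48e-05). MLPH fell by 3.51 ± 0.36 (adjusted p = 2.27e-05), and AADAC, a deacetylase of the endoplasmic reticulum, fell by 4.24 ± 0.90 (adjusted p = 0.00675). The late mean of AADAC, 3.25, lay below the median of the viral-genome probe sets, 3.42, so it was not above background there.

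All 17 cell proliferation genes fell at the late stage, over all probe sets as well as adjusted over the list alone, and the list was called lower (adjusted p = 2.89e-15). With an estimated correlation its adjusted p = 0.183. CCNB1 fell by 2.48 ± 0.23 (adjusted p = 1.44e-05), TOP2A fell by 1.70 ± 0.28 (adjusted p = 0.00103). CDK1, the kinase of mitosis, fell by 1.52 ± 0.28 (adjusted p = 0.00278) and MKI67 fell by 1.38 ± 0.26 (adjusted p = 0.00264). Of the 13 endothelial markers 3 rose over all probe sets and 6 adjusted over the list alone (list adjusted p = 0.0139, and adjusted p = 0.795 with an estimated correlation). The 3 were MMRN2 (0.53 ± 0.13, adjusted p = 0.0187), TEK (0.73 ± 0.18, adjusted p = 0.0176) and EMCN (0.80 ± 0.23, adjusted p = 0.0432), all chosen after their values were seen. KDR rose by 1.13 ± 0.25 (adjusted p = 0.00940). Of the 16 macrophage markers 2 rose over all probe sets and 2 adjusted over the list alone (list adjusted p = 0.0149, and adjusted p = 0.754 with an estimated correlation): CD74, the invariant chain of class II antigen presentation (1.58 ± 0.31, adjusted p = 0.00377), and CYBB, part of the phagocyte oxidase (1.31 ± 0.33, adjusted p = 0.0188). Of the 13 lysosome and autophagy genes 3 rose by both counts (list adjusted p = 0.0254, and adjusted p = 0.538 with an estimated correlation): the cathepsins CTSK (1.91 ± 0.40, adjusted p = 0.00612) and CTSS (1.78 ± 0.37, adjusted p = 0.00621), and SQSTM1, an autophagy receptor chosen after its value was seen (0.43 ± 0.12, adjusted p = 0.0411).

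Other members of the fixed lists passed while their lists were not called. APOE, an apolipoprotein of cholesterol efflux, rose by 1.04 ± 0.13 (adjusted p = 0.000138). MYLIP, a ubiquitin ligase, rose by 1.07 ± 0.15 (adjusted p = 0.000372), and LPCAT3, a phospholipid acyltransferase, fell by 1.20 ± 0.20 (adjusted p = 0.00125). MMP9, a gelatinase, rose by 2.35 ± 0.43 (adjusted p = 0.00252). TNFSF10, a death ligand, rose by 1.85 ± 0.37 (adjusted p = 0.00430) and ZFP36 rose by 1.69 ± 0.32 (adjusted p = 0.00282). FSTL3 fell by 2.56 ± 0.21 (adjusted p = 5.29e-06). The epithelial keratin KRT8 fell by 2.42 ± 0.40 (adjusted p = 0.00106). The metallothionein MT2A fell by 1.76 ± 0.31 (adjusted p = 0.00176) and the glutathione transferase GSTA1 fell by 1.75 ± 0.35 (adjusted p = 0.00470).

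Over all probe sets 1903 were higher and 2091 lower at the late stage, 900 by at least 2-fold, and the groups did not overlap for 13.7% of probe sets (2.86% by chance). The 3994 calls became 2588 without early replicate 3. CYBB failed without early replicates 2 or 3 or late replicates 2, 3 or 4 (adjusted p = 0.0524 to 0.0592) and on the mean of its probe sets (adjusted p = 0.103). TEK failed without early replicates 2 or 4 or late replicate 4 (adjusted p = 0.0521 to 0.0661). MMRN2 failed without early replicate 1 or late replicate 4 (adjusted p = 0.0591 and 0.0588). EMCN failed without early replicates 2, 3 or 4 or any late replicate (adjusted p = 0.0551 to 0.124). SQSTM1 failed without the same 7 arrays (adjusted p = 0.0534 to 0.130). RLN2 was at 6.49 without early replicate 2 and 5.00 without early replicate 3, SERPINA4 at 6.098 without early replicate 2, DEFB122 at -3.69 without late replicate 1, and AADAC at -3.35 without early replicate 1 and -5.59 without early replicate 2.

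The steps from mid to mid-late and from mid-late to late ask where the turn towards regression shows. From mid to mid-late 6 probe sets were lower and 0 higher in limma, with 3458 at an unadjusted p under 0.05. Of the 6, 3 belonged to HIPK2, a kinase that acts in stress responses: they changed by -1.04 ± 0.16 (adjusted p = 0.0459), -1.23 ± 0.16 (adjusted p = 0.0136) and -1.54 ± 0.23 (adjusted p = 0.0317), and none of its 7 probe sets was called higher. NKAIN1, which binds a subunit of the sodium pump and was chosen after its value was seen, was at -0.55 ± 0.08 (adjusted p = 0.0156), and 2 called probe sets had no gene name. Macrophage markers (adjusted p = 0.0195, and adjusted p = 0.778 with an estimated correlation) and complement genes (adjusted p = 0.0266, and adjusted p = 0.440 with an estimated correlation) were called higher with 0 of 16 and 0 of 12 members past limma's test, none adjusted over the list alone, and 1 macrophage marker higher and 1 complement gene lower at an unadjusted p under 0.05. Erythrocyte markers were called lower (adjusted p = 0.0195, and adjusted p = 0.356 with an estimated correlation), with 0 of 5 past limma's test, 2 adjusted over the list alone and 3 at an unadjusted p under 0.05. The groups did not overlap for 4.79% of probe sets (2.86% by chance). All 4 mid arrays and 1 of the 4 mid-late arrays lay in the low mitochondrial group. The 6 calls became 2 without mid replicate 3, 21 without mid-late replicate 1, and 1 without mid-late replicate 3 or without mid-late replicate 4. They became 26 with array weights and 1 on the 8 arrays of the 2 stages, and 1 with a term for the mitochondrial groups, chosen after seeing the data. At its representative probe set HIPK2 failed without mid replicates 1, 3 or 4 or mid-late replicates 2, 3 or 4 (adjusted p = 0.0607 to 0.309) and with cyclic loess scaling (adjusted p = 0.0679). NKAIN1 failed without mid replicates 2 or 3 or mid-late replicates 2, 3 or 4 (adjusted p = 0.0531 to 0.121).

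From mid-late to late DEFB122 fell by 3.097 ± 0.44 (adjusted p = 0.0307). A probe set of NPR3, the clearance receptor of natriuretic peptides, fell by 2.02 ± 0.29 (adjusted p = 0.0307); it was chosen after its value was seen, and the representative probe set of NPR3 was at -2.02 with an adjusted p of 0.143. HSD3B2 was at -2.05 ± 0.37 (adjusted p = 0.0816), CD68 at 1.06 ± 0.27 (adjusted p = 0.253) and TOP2A at -1.14 ± 0.28 (adjusted p = 0.237), none past the test. Macrophage markers were called higher (adjusted p = 5.31e-09, and adjusted p = 0.183 with an estimated correlation), with 0 of 16 past limma's test over all probe sets, 9 adjusted over the list alone and 10 at an unadjusted p under 0.05. Lysosome genes (adjusted p = 0.000162, and adjusted p = 0.183 with an estimated correlation) had 0 of 13 past limma's test, 3 higher adjusted over the list alone and 3 at an unadjusted p under 0.05. Complement genes (adjusted p = 0.00218, and adjusted p = 0.191 with an estimated correlation) had 0 of 12, 2 higher adjusted over the list alone and 6 at an unadjusted p under 0.05. Cell proliferation genes were called lower (adjusted p = 4.71e-09, and adjusted p = 0.191 with an estimated correlation), with 0 of 17 past limma's test, 5 adjusted over the list alone and 8 at an unadjusted p under 0.05. Progesterone synthesis genes were called lower (adjusted p = 0.0443, and adjusted p = 0.459 with an estimated correlation), with 0 of 10, 2 adjusted over the list alone and 2 at an unadjusted p under 0.05. The mitochondrial respiratory chain was called lower (adjusted p = 0.00639, and adjusted p = 0.778 with an estimated correlation), with 0 of 19, none adjusted over the list alone and 4 at an unadjusted p under 0.05.

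Over all probe sets 2 were higher and 4 lower at the late stage, with 3369 at an unadjusted p under 0.05, and 4 of the 6 had no gene name. The share of higher calls was 33.3%, against 45.5% of 11 calls with cyclic loess scaling and 50% of 4 calls with median centring. The groups did not overlap for 5.67% of probe sets (2.86% by chance). The 6 calls became 83 without late replicate 1, 2 without mid-late replicate 3 or late replicate 4, and 0 without mid-late replicates 2 or 4 or late replicate 3. They became 89 on the 8 arrays of the 2 stages, 185 with array weights, 13 without dim probe sets, 11 with cyclic loess scaling and 11 with a trended and robust prior. Chosen after seeing the data, they became 53 without very-late replicates 1 and 2, 36 without all very-late arrays and 3 on the 13 arrays of the high mitochondrial group. HSD3B2 passed without late replicate 1 (-1.49, adjusted p = 0.00519, against 0.0566 to 0.298 over its other fits). DEFB122 failed without any 1 of the mid-late replicates or late replicates 3 or 4 (adjusted p = 0.0519 to 0.190), and was at -2.50 without late replicate 1.

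The comparison of the very-late with the late stage asks what happens as the tissue breaks down. STAR fell by 4.22 ± 0.38 (18.6-fold, adjusted p = 4.33e-07), HSD3B2 fell by 3.30 ± 0.37 (adjusted p = 6.79e-06). HSD11B1 fell by 3.85 ± 0.32 (adjusted p = 1.82e-07) and STARD4, which moves cholesterol between membranes, fell by 3.05 ± 0.16 (adjusted p = 1.78e-09). Of the 10 progesterone synthesis genes 7 fell over all probe sets, and adjusted over the list alone 7 fell and 1 rose (list adjusted p = 2.34e-06, and adjusted p = 0.161 with an estimated correlation). CYP19A1 fell by 5.02 ± 0.47 (adjusted p = 7.04e-07). Of the 10 androgen and estrogen synthesis genes 6 fell over all probe sets and 7 adjusted over the list alone (list adjusted p = 0.000537, and adjusted p = 0.183 with an estimated correlation). CYP17A1, which makes androgens, was at -1.30 ± 0.66 (adjusted p = 0.245) with overlapping groups, and passed without very-late replicate 4 (-2.10, adjusted p = 0.0105, against 0.169 to 0.629 over its other fits). Of the 9 granulosa-lutein markers 6 fell by both counts (list adjusted p = 0.000504, and adjusted p = 0.183 with an estimated correlation). The inhibin subunits INHA and INHBA fell by 3.63 ± 0.50 (adjusted p = 5.43e-05) and by 3.64 ± 0.51 (adjusted p = 6.72e-05), and the nuclear receptor NR5A2 fell by 2.73 ± 0.43 (adjusted p = 0.000228). Without very-late replicate 2 INHA was at -2.80 and NR5A2 at -2.07.

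Cholesterol synthesis genes were called lower, and genes of lipoprotein uptake and cholesterol efflux higher, each with some members that did not pass and each call lost with an estimated correlation. Of the 15 cholesterol synthesis genes 10 fell by both counts (list adjusted p = 4.54e-08, and adjusted p = 0.207 with an estimated correlation). DHCR7, EBP and CYP51A1, enzymes of late steps, fell by 3.21 ± 0.43 (adjusted p = 3.86e-05), by 2.61 ± 0.28 (adjusted p = 3.79e-06) and by 2.54 ± 0.29 (adjusted p = 8.49e-06). Of the 5 lipoprotein uptake genes 3 rose over all probe sets, and 3 rose and 1 fell adjusted over the list alone (list adjusted p = 0.0403, and adjusted p = 0.189 with an estimated correlation). The 3 were the scavenger receptor CD36 (3.43 ± 0.27, adjusted p = 9.57e-08), the lysosomal acid lipase LIPA (1.76 ± 0.14, adjusted p = 9.92e-08) and the lysosomal cholesterol carrier NPC2, chosen after its value was seen (0.79 ± 0.14, adjusted p = 0.000800). Of the 13 genes of cholesterol efflux and LXR targets 5 rose and 1 fell by both counts (list adjusted p = 0.00182, and adjusted p = 0.183 with an estimated correlation). LPL, a lipoprotein lipase, rose by 4.34 ± 0.24 (adjusted p = 2.86e-09). Of its 4 probe sets 2 were called higher, and on their mean the change was much smaller. The liver X receptor NR1H3 rose by 1.53 ± 0.24 (adjusted p = 0.000194) and the phospholipid carrier PLTP rose by 1.00 ± 0.13 (adjusted p = 2.44e-05). The other 3, chosen after their values were seen, were MYLIP (0.90 ± 0.15, adjusted p = 0.000472), the transporter ABCA9 (0.97 ± 0.21, adjusted p = 0.00360, from a late mean of 3.40 that is not above background) and APOA1 (-0.96 ± 0.29, adjusted p = 0.0320). APOA1 failed without late replicates 2, 3 or 4 or very-late replicate 2 (adjusted p = 0.0567 to 0.0917) and with cyclic loess scaling (adjusted p = 0.0754). ABCA1, an exporter of cholesterol, was at 0.20 ± 0.09 (adjusted p = 0.166) with overlapping groups, and passed without late replicate 1 (0.29, adjusted p = 0.00980, against 0.118 to 0.433 over its other fits).

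Macrophage, lysosome and cytokine genes were called higher, each with some members that did not pass and each call lost with an estimated correlation. Of the 16 macrophage markers 9 rose over all probe sets, and 11 rose and 1 fell adjusted over the list alone (list adjusted p = 0.000265, and adjusted p = 0.459 with an estimated correlation). CYBB rose by 3.54 ± 0.33 (adjusted p = 6.75e-07). The signalling adaptor TYROBP rose by 2.76 ± 0.31 (adjusted p = 5.85e-06), CD68 by 2.70 ± 0.27 (adjusted p = 1.84e-06) and MS4A7 by 2.54 ± 0.37 (adjusted p = 0.000111). Of the 13 lysosome and autophagy genes 8 rose over all probe sets and 9 adjusted over the list alone (list adjusted p = 0.000218, and adjusted p = 0.189 with an estimated correlation), among them CTSK (2.61 ± 0.40, adjusted p = 0.000168), CTSS (2.47 ± 0.37, adjusted p = 0.000143) and CTSL (2.08 ± 0.20, adjusted p = 1.08e-06). Of the 22 cytokine and chemokine genes 6 rose and 1 fell by both counts (list adjusted p = 0.0139, and adjusted p = 0.538 with an estimated correlation). The chemokines CCL2 and CCL3 rose by 5.05 ± 0.59 (adjusted p = 1.06e-05) and by 4.16 ± 0.35 (adjusted p = 2.44e-07), and the interleukin-1 antagonist IL1RN rose by 2.45 ± 0.55 (adjusted p = 0.00478). The 1 that fell was CCL8, chosen after its value was seen (-0.76 ± 0.19, adjusted p = 0.0107); another of its 3 probe sets was called higher, and the mean of the 3 was higher by 0.18 (adjusted p = 0.449). The complement genes CFD and C5AR1 rose by 1.98 ± 0.34 (adjusted p = 0.000521) and by 2.66 ± 0.34 (adjusted p = 2.80e-05), while their list was not called. Very-late replicates 1 and 2 are the arrays set apart by the GAPDH signal and by correlation, and the counts for these lists include them.

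Pericyte, respiratory chain and oxidative stress genes were called lower, each with some members that did not pass and each call lost with an estimated correlation. Of the 10 pericyte and smooth muscle markers 5 fell over all probe sets and 6 adjusted over the list alone (list adjusted p = 0.0106, and adjusted p = 0.677 with an estimated correlation). The smooth muscle actin ACTG2 fell by 2.15 ± 0.37 (adjusted p = 0.000469). MCAM, an adhesion molecule of vessel walls, fell by 1.94 ± 0.27 (adjusted p = 5.68e-05) and the myosin light chain MYL9 fell by 1.63 ± 0.25 (adjusted p = 0.000179). The other 2, chosen after their values were seen, were the proteoglycan CSPG4 (-0.46 ± 0.11, adjusted p = 0.00909) and TAGLN (-0.90 ± 0.29, adjusted p = 0.0499). The groups overlapped for TAGLN, which failed without late replicates 1, 3 or 4 or very-late replicates 1, 3 or 4 (adjusted p = 0.0836 to 0.174) and with cyclic loess scaling (adjusted p = 0.0899). Of the 14 fibroblast and collagen matrix genes 5 fell and 1 rose by both counts, and the list was not called (adjusted p = 0.1004). COL1A1, a chain of collagen I, fell by 1.51 ± 0.24 (adjusted p = 0.000234) and TIMP1, an inhibitor of matrix proteases, fell by 1.11 ± 0.07 (adjusted p = 1.14e-08). Of the 20 matrix proteases and inhibitors 5 rose and 5 fell over all probe sets, and 6 rose and 5 fell adjusted over the list alone, with the list not called (adjusted p = 0.925). The proteases ADAMTS4 and ADAMTS1 fell by 2.37 ± 0.37 (adjusted p = 0.000223) and by 2.04 ± 0.36 (adjusted p = 0.000647), while MMP9 rose by 1.94 ± 0.43 (adjusted p = 0.00466). Of the 19 respiratory chain genes 10 fell over all probe sets, and 13 fell and 1 rose adjusted over the list alone (list adjusted p = 0.000504, and adjusted p = 0.579 with an estimated correlation), among them UQCRC2 of complex III (-1.24 ± 0.21, adjusted p = 0.000532) and SDHC of complex II (-1.13 ± 0.21, adjusted p = 0.000862). The mean z score of the list was -0.145 in very-late replicate 2, against -1.56 to -1.02 in the other 3 very-late arrays. Of the 13 oxidative stress genes 6 fell and 1 rose by both counts (list adjusted p = 0.0205, and adjusted p = 0.183 with an estimated correlation): the mitochondrial superoxide dismutase SOD2 rose by 2.78 ± 0.23 (adjusted p = 1.81e-07), and the peroxiredoxin PRDX4 fell by 1.46 ± 0.13 (adjusted p = 2.96e-07) and the transferase GSTA4 by 1.71 ± 0.29 (adjusted p = 0.000443).

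Further genes with large changes belonged to lists that were not called, or to none. WNT5A, a secreted Wnt ligand, fell by 3.64 ± 0.31 (adjusted p = 2.76e-07). HPGD, which inactivates prostaglandins, fell by 3.19 ± 0.59 (adjusted p = 0.000916) and the prolactin receptor PRLR fell by 1.67 ± 0.33 (adjusted p = 0.00165). The transcription factors EGR2 and ATF3 rose by 3.15 ± 0.52 (adjusted p = 0.000373) and by 1.65 ± 0.26 (adjusted p = 0.000236), and BCL2L11, which promotes apoptosis, rose by 1.15 ± 0.24 (adjusted p = 0.00301). VEGFB, a vascular growth factor, rose by 1.18 ± 0.16 (adjusted p = 4.48e-05), as did the co-receptor NRP2, by 1.33 ± 0.13 (adjusted p = 1.97e-06). CHIT1 rose by 4.04 ± 0.56 (adjusted p = 6.26e-05). PLA2G7, a phospholipase of macrophages, rose by 4.07 ± 0.25 (adjusted p = 8.22e-09) and SLAMF7, a receptor of immune cells, by 4.03 ± 0.28 (adjusted p = 2.23e-08). ATXN7 fell by 4.97 ± 0.20 (adjusted p = 8.10e-11). The drug-metabolising CYP3A4 fell by 4.91 ± 0.59 (adjusted p = 1.33e-05). SERPINA4 fell by 4.79 ± 0.91 (adjusted p = 0.00116) and TLCD4 fell by 4.74 ± 0.46 (adjusted p = 1.29e-06). TOP2A fell by 1.19 ± 0.28 (adjusted p = 0.00668). Without very-late replicate 2 CYP3A4 was at -4.18 and SERPINA4 at -4.00, and without late replicate 1 HPGD was at -3.80 and EGR2 at 3.84. The late mean of EGR2, 4.64, lay within its SD of background.

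Over all probe sets 3559 were higher and 3703 lower at the very-late stage, 2330 by at least 2-fold, and the groups did not overlap for 15.2% of probe sets (2.86% by chance). With very-late replicates 1 and 2 both left out, an alternative chosen after seeing the data, 4704 of the 52707 probe sets passed in place of 7262, and 4574 on the 8 arrays of the 2 stages. With median centring 3018 were higher and 3998 lower, and with cyclic loess scaling 3609 and 3527, so that the balance of higher and lower calls depends on the scaling.

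**Figure D3:**
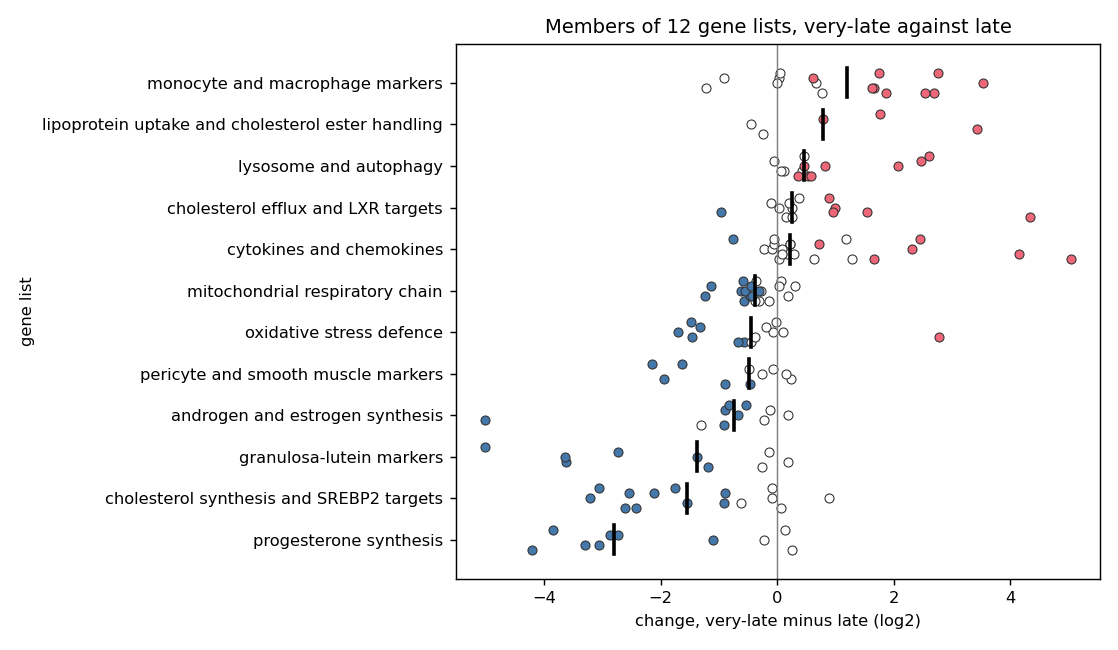
Change from late to very-late (log2) of each measured member of the 12 lists called in that comparison, filled in red or blue where the member passed over all probe sets and open where it did not, with the list's median as a black line. The median is lowest for progesterone synthesis, at -2.80, and highest for the macrophage markers, at 1.20.

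The comparison of the very-late with the early stage sets the ends of luteal life side by side. HSD11B1 fell by 6.12 ± 0.32 (adjusted p = 5.84e-10). HSD3B2 fell by 5.95 ± 0.37 (61.8-fold, adjusted p = 4.74e-09) and STAR fell by 4.05 ± 0.38 (adjusted p = 4.01e-07). DEFB122 fell by 6.47 ± 0.44 (adjusted p = 1.35e-08). AREG, a growth factor of the EGF family, fell by 6.32 ± 0.46 (adjusted p = 2.70e-08). MRAP, which serves melanocortin receptors, fell by 4.79 ± 0.22 (adjusted p = 1.64e-10) and NANOS1 fell by 4.70 ± 0.46 (adjusted p = 7.09e-07). CHIT1 rose by 7.32 ± 0.56 (160-fold, adjusted p = 4.70e-08). The macrophage protease ADAMDEC1 rose by 5.41 ± 0.43 (adjusted p = 7.41e-08), PRAM1 by 5.03 ± 0.25 (adjusted p = 3.44e-10) and SLAMF7 by 5.02 ± 0.28 (adjusted p = 1.11e-09).

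Of the 10 progesterone synthesis genes 8 fell and 1 rose by both counts (list adjusted p = 4.94e-06, and adjusted p = 0.161 with an estimated correlation). The 1 was STARD3, chosen after its value was seen, with overlapping groups (0.29 ± 0.09, adjusted p = 0.0295); it failed without early replicates 1, 2 or 4 or very-late replicates 1 or 2 (adjusted p = 0.0683 to 0.107). Of the 10 androgen and estrogen synthesis genes 8 fell by both counts (list adjusted p = 0.000265, and adjusted p = 0.183 with an estimated correlation), among them CYP19A1 (-2.99 ± 0.47, adjusted p = 0.000128). Of the 9 granulosa-lutein markers 6 fell over all probe sets and 7 adjusted over the list alone (list adjusted p = 0.00184, and adjusted p = 0.196 with an estimated correlation), among them INHA (-3.40 ± 0.50, adjusted p = 7.04e-05, and -2.56 without very-late replicate 2). Of the 15 cholesterol synthesis genes 11 fell over all probe sets and 13 adjusted over the list alone (list adjusted p = 3.21e-08, and adjusted p = 0.202 with an estimated correlation), among them DHCR7 (-4.05 ± 0.43, adjusted p = 1.77e-06) and SQLE (-3.55 ± 0.28, adjusted p = 7.26e-08, to a mean of 3.55 within its SD of background). Of the 5 lipoprotein uptake genes 3 rose and 1 fell by both counts (list adjusted p = 0.0172, and adjusted p = 0.183 with an estimated correlation): CD36 (4.00 ± 0.27, adjusted p = 9.24e-09), LIPA (1.91 ± 0.14, adjusted p = 2.22e-08) and NPC2 (1.55 ± 0.14, adjusted p = 4.01e-07) rose, and the cholesterol carrier NPC1, chosen after its value was seen, fell (-0.93 ± 0.17, adjusted p = 0.000453). Of the 13 efflux genes 8 rose and 2 fell by both counts (list adjusted p = 0.00249, and adjusted p = 0.183 with an estimated correlation). LPL rose by 4.90 ± 0.24 (adjusted p = 3.47e-10), with 2 of its 4 probe sets called higher. APOA1 (-1.83 ± 0.29, adjusted p = 0.000146) and LPCAT3, chosen after its value was seen (-1.30 ± 0.20, adjusted p = 0.000118), fell.

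Of the 16 macrophage markers 10 rose over all probe sets and 11 adjusted over the list alone (list adjusted p = 2.16e-06, and adjusted p = 0.222 with an estimated correlation), among them CYBB (4.84 ± 0.33, adjusted p = 1.09e-08), CD68 (3.31 ± 0.27, adjusted p = 1.00e-07) and TYROBP (2.95 ± 0.31, adjusted p = 1.61e-06). Of the 13 lysosome genes 9 rose over all probe sets and 11 adjusted over the list alone (list adjusted p = 4.53e-06, and adjusted p = 0.183 with an estimated correlation), among them CTSK (4.52 ± 0.40, adjusted p = 2.43e-07) and CTSS (4.25 ± 0.37, adjusted p = 2.21e-07). Of the 22 cytokine genes 10 rose and 2 fell over all probe sets, and 12 rose and 2 fell adjusted over the list alone (list adjusted p = 0.00565, and adjusted p = 0.484 with an estimated correlation). CCL3 rose by 4.98 ± 0.35 (adjusted p = 1.81e-08) and CCL2 by 3.99 ± 0.59 (adjusted p = 8.10e-05, and 4.58 without early replicate 4). The 2 that fell, chosen after their values were seen, were CCL8 (-1.17 ± 0.19, adjusted p = 0.000210, but 0.267 for the mean of its 3 probe sets) and CCL21 (-1.36 ± 0.30, adjusted p = 0.00278). Of the 12 complement genes 4 rose over all probe sets and 5 adjusted over the list alone (list adjusted p = 0.0430, and adjusted p = 0.492 with an estimated correlation): C5AR1 (2.60 ± 0.34), CFD (1.98 ± 0.34), C7 (1.93 ± 0.42) and CFB (1.44 ± 0.24), the last with an adjusted p of 0.310 for the mean of its 3 probe sets. Very-late replicates 1 and 2, apart in the GAPDH signal and in correlation, are among the arrays behind these counts.

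Of the 17 cell proliferation genes 15 fell by both counts (list adjusted p = 9.43e-09, and adjusted p = 0.196 with an estimated correlation), among them CCNB1 (-2.94 ± 0.23, adjusted p = 4.91e-08), TOP2A (-2.89 ± 0.28, adjusted p = 6.35e-07) and MKI67 (-1.67 ± 0.26, adjusted p = 0.000108). Of the 19 respiratory chain genes 11 fell by both counts (list adjusted p = 0.00179, and adjusted p = 0.684 with an estimated correlation). Of the 13 oxidative stress genes 8 fell and 1, SOD2 (3.33 ± 0.23, adjusted p = 1.35e-08), rose by both counts (list adjusted p = 0.0195, and adjusted p = 0.183 with an estimated correlation). Of the 10 pericyte markers 6 fell by both counts (list adjusted p = 0.0439, and adjusted p = 0.782 with an estimated correlation), among them ACTG2 (-2.47 ± 0.37, adjusted p = 7.71e-05). Outside the called lists MMP9 rose by 4.29 ± 0.43 (adjusted p = 1.10e-06) and IGF2R, the clearance receptor of insulin-like growth factor 2, by 1.40 ± 0.12 (adjusted p = 2.23e-07), while IGFBP3 fell by 2.01 ± 0.37 (adjusted p = 0.000631). WNT5A fell by 4.14 ± 0.31 (adjusted p = 3.52e-08), TIMP1 fell by 1.12 ± 0.07 (adjusted p = 6.52e-09) and COL1A1 fell by 1.73 ± 0.24 (adjusted p = 3.66e-05).

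Over all probe sets 4981 were higher and 4852 lower at the very-late stage, 2958 by at least 2-fold, and the groups did not overlap for 17.8% of probe sets (2.86% by chance). With very-late replicates 1 and 2 both left out, an alternative chosen after seeing the data, 8335 passed in place of 9833, and 6178 on the 8 arrays of the 2 stages. With median centring 4107 were higher and 5630 lower, so that this balance turned with the scaling.

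Between the calls of mid against early and those of late against mid-late, 1 probe set was shared, lower in both and with no gene name, where chance gives 0.00698. That number assumes independent calls, but the 2 comparisons share 1 estimate of the spread. With only 6 calls in late against mid-late, no excess is read from it.

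**Figure D4:**
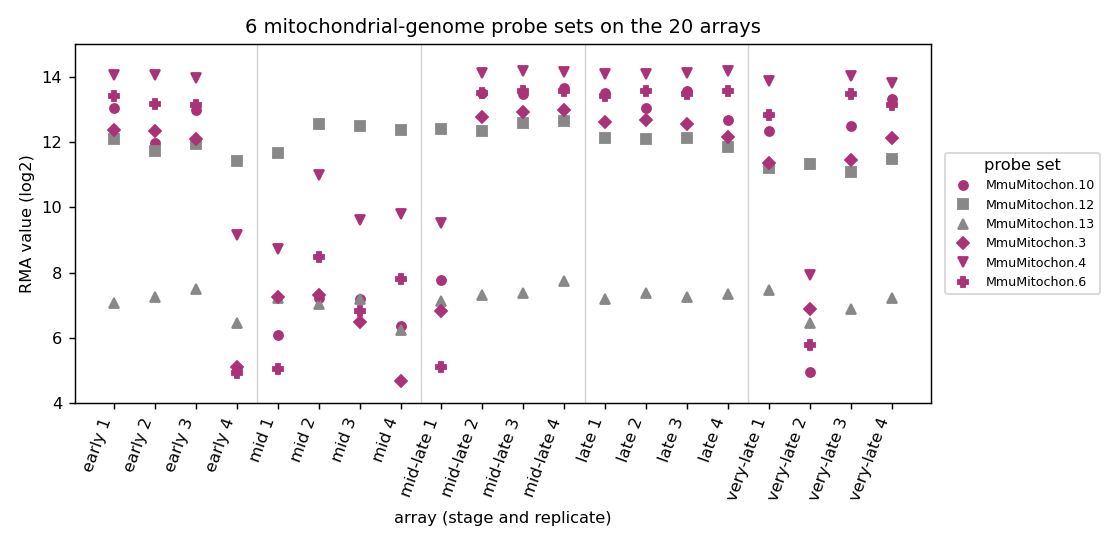
RMA values (log2) of the 6 mitochondrial-genome probe sets on each of the 20 arrays, with the 4 that split the arrays and the other 2 in separate colours. The mean of the 4 lies at 6.07 to 8.50 on 7 arrays, all 4 mid arrays among them, and at 12.6 to 13.6 on the other 13.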

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

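The tests on mitochondrial probe sets, on the share of luteal cells, without very-late replicates 1 and 2 and without all very-late arrays were chosen after the result was seen; the other tests in this part were planned. In 280 groups of 4 arrays, 28 (10%) held 1 array set apart from its stage, by a gap to the nearest array beyond Dixon's 95% critical share of the range, where chance flags about 1 in 20 groups, or 14. The groups are not independent. The 28 include 4 mitochondrial probe sets that vary together, each flagged in early replicate 4, mid-late replicate 1 and very-late replicate 2. So the excess over 14 does not show that the single values listed later are beyond chance.

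In early replicate 4, 4 probe sets of the mitochondrial genome read 5.07, 5.105, 9.145 and 4.938, against 11.98 to 14.06 in the other early arrays. In mid-late replicate 1 they read 7.76, 6.811, 9.516 and 5.103, against 12.77 to 14.17, and in very-late replicate 2 4.969, 6.878, 7.916 and 5.776, against 11.34 to 14.03. With the 4 mid arrays, 7 arrays lay low and 13 high, with a gap of 4.09 between their means of the 4 probe sets. All 4 mid arrays were low and all 4 late arrays high, so they add nothing to differences within stages. The within-stage values below rest on early replicate 4, mid-late replicate 1 and very-late replicate 2 against the other arrays of their stages. For these, the 4 probe sets differed by 5.16 ± 0.302 or more, and the other 2 mitochondrial probe sets by 0.636 ± 0.175 at most. This argues against an equally lower amount of all mitochondrial RNA, but only on those 2 probe sets. Their place on the mitochondrial genome was not checked, so a lower amount of part of this RNA stays open. A processing lot of the arrays may be the cause: within stages 68 probe sets not named for the mitochondrial genome differed with this split, 39 of them with 1 gene symbol. Of the 64 splits with as many arrays per stage, 1, the real one, called as many (highest other 8). These calls cannot tell a lot from a difference between animals, since either could move other probe sets. Of the 68, 6 unnamed ones correlated with the 4 at r over 0.9 and, with no sequences used, could be mitochondrial too. A mitochondrial sequence variant between animals also stays open: an exact two-sided test of the split over the 5 stages gave p = 0.0609, which does not show an even spread.

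Macrophage markers were called higher at very-late than at late, with 9 of 16 past the test over all probe sets and the call lost with an estimated correlation (adjusted p = 0.459). A lower share of luteal cells alone is argued against: macrophage markers changed by 1.15 (SD 1.37, n = 16 genes) and the markers of 3 other cell types by -0.445 (SD 0.667, n = 37 genes), a difference of 1.60 with a permutation p over genes of 1e-05, the smallest possible. Genes are not independent replicates. Degraded RNA in very-late replicate 1 is argued against as well, since without very-late replicate 1 all 9 macrophage markers were called higher, and 8 without very-late replicate 2. More macrophages in the tissue, or more of these transcripts per macrophage, may be the cause and were not tested.

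Few probe sets differed between mid-late and late. Late replicate 1 correlated with its stage at 0.9887, against 0.995 to 0.9959 in the others. That late replicate 1 is apart from late 2 to 4 may be a cause: without late replicate 1, 83 probe sets were called in place of 6. It is not the only open one, since fits that keep late replicate 1 called 89 on the 8 arrays of the 2 stages and 53 without very-late replicates 1 and 2. With array weights 185 were called, but these gave late replicate 1 a weight of 0.671, against 1.10 to 1.40 in late 2 to 4. That count therefore does not separate the causes. Without the 4 very-late arrays, and with late replicate 1 kept, 36 were called in place of 6. Spread shared with the very-late arrays may therefore be a cause too. The root mean square SD over probe sets was 0.285 at the very-late stage, against 0.177 at mid-late and 0.181 at late. How much each cause adds was not tested.

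Another mitochondrial probe set was at 11.85 in late replicate 4, against 12.08 to 12.12. PECAM1 was at 9.774 in mid replicate 2, against 9.37 to 9.4, and at 9.388 in mid-late replicate 1, against 9.857 to 9.937. The actin signal at the 3' end exceeded that at the 5' end by 0.973 in mid replicate 2, against -0.017 to 0.115. CYP19A1 was at 7.292 in very-late replicate 4, against 5.789 to 5.994, and COL1A1 at 10.51 in very-late replicate 3, against 9.47 to 9.636. The other values are means of z scores over a list's members. Surface epithelium markers were at 0.9575 in early replicate 1, against -0.4365 to -0.2193. In mid replicate 3 pericyte markers were at -0.3625, against 0.3328 to 0.4038. In mid replicate 4 macrophage markers were at -1.13, against -0.5803 to -0.5039, and theca and stroma markers at 0.4138, against -0.4401 to -0.3095. In mid-late replicate 1 apoptosis genes were at -0.3158, against -0.09207 to -0.07875. In late replicate 3 cholesterol synthesis genes were at 0.3472, against -0.02159 to 0.01457, and prostaglandin genes at -0.5426, against -0.1666 to -0.104. In very-late replicate 2 theca and stroma markers were at -1.399, against 0.2098 to 0.4316, and Wnt pathway genes at -1.029, against 0.02508 to 0.1655.

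Other splits of the same arrays tested whether chance can be excluded. For any difference between stages, 1 of 100 groupings, the real one with 11311, called as many (highest other 22), which argues against chance. Only the real split, 1 of 35, called as many for mid against early (191, highest other 32), mid-late against early (1964, 12) and late against early (3994, 2). The same held for very-late against early (9833, 1116), late against mid-late (6, 4) and very-late against late (7262, 191). A share of 1 in 35 is the smallest that 35 splits can give. It was not adjusted over the comparisons, so it makes chance less likely but does not exclude it. For late against mid-late, 6 calls against 4 are too close to argue against chance. For mid-late against mid, 3 of 35 splits called as many as the real 6, so chance is not excluded. The highest, 54, set mid replicates 1 to 3 and mid-late replicate 1 against the rest. What this split reflects was not tested. It put 4 of the 5 arrays of the low mitochondrial group on one side, and with a term for that group the real comparison called 1 probe set.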

How the results depend on the processing

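The fits with a term for the mitochondrial split, on its 13 high arrays and without very-late arrays were chosen after seeing the data; the rest were planned. Counts run in the order mid, mid-late, late and very-late against early, mid-late against mid, late against mid-late and very-late against late, and the cause was not tested unless stated. No named gene past the test changed direction under a replicate block, cyclic loess or leaving out 1 array, while some that did not pass changed sign, such as CYP17A1 in very-late against early (-1.16 to 0.37 without 1 array). Further, the medians of all probe sets moved by less than 0.1 under either scaling. On the mean of all its probe sets CCL8 reversed in very-late against late, to 0.1761, and so did DKK3, which the rule takes, there (0.2469) and in very-late against early (0.4222). Some named genes kept their direction with a much smaller change on that mean, such as LPL in very-late against late (2.20). Of 343 pairs of gene and comparison, that mean ended 5 calls, a replicate block 16 and cyclic loess 3, and leaving out 1 array ended 209 of 2744. The labels state no pairing of the arrays by replicate number, and the residuals gave no sign of one, which does not exclude it. Correlations of same-number residuals ran from -0.2082 to 0.2143 in 28 pairs of arrays, with the own number best in 7. A log2 of the value plus 16 was not run, since the values are log2 already, and a fit on the 7 low arrays alone was not run.

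Counts that moved by over 1.5 times were 324 and 13 (mid against early, late against mid-late) without dim probe sets, 11 (late against mid-late) with cyclic loess and 11 with a trended prior. With array weights they were 534, 3758, 26 and 185 (mid and mid-late against early, mid-late against mid, late against mid-late), and with a replicate block 81 and 3 (mid against early, late against mid-late). Per gene, where fewer features are tested, they were 5085 for any difference, then 1178, 2029, 4408, 2, 16 and 3326 for all but mid against early. Stricter thresholds gave fewer by construction: 4249, 63, 400, 900, 2958, 3 and 2330 at 2-fold (all but late against mid-late), and 7295, 16, 528, 1748, 6447, 1, 1 and 4373 at an adjusted p under 0.01. Fits on 8 arrays gave 25, 6178, 1, 89 and 4574 (mid and very-late against early and the last 3). A term for the mitochondrial split gave 19 (mid against early) and 1 (mid-late against mid), and the 13 high arrays 3 (late against mid-late). Without very-late replicates 1 and 2 there were 614, 3231, 53 and 4704, and without all very-late arrays 4679 for any difference, 593, 3197 and 36.

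Leaving out 1 array gave 10236 to 11323 for any difference, then 30 to 249, 806 to 1826, 2588 to 3912, 8458 to 9570, 1 to 21, 0 to 83 and 5526 to 7457; the lows were without early replicate 3, mid replicate 3, mid-late replicate 3, early replicate 3, early replicate 3, mid-late replicates 3 and 4, late replicate 3 (also mid-late replicates 2 and 4) and late replicate 3.

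With an estimated correlation each of the 17 called lists had 0 calls over the 7 comparisons. With fry receptors and endothelial markers had 0, macrophage markers 3, erythrocyte markers 1, prostaglandin genes 2, angiogenic genes 1, B and plasma cell markers 2, activin genes 2, the IGF system 1 and the Wnt pathway 1. The mean of probe sets gave receptors 0, complement 1 and the IGF system 1, leaving out dim probe sets gave lipoprotein uptake 1, receptors 0 and pericytes 1, and the replicate block gave lipoprotein uptake 1, the IGF system 1 and immediate early genes 1. Signal over background limits dim probe sets: 683 of viral genomes had a median of 3.42, against 3.92 for the arrays.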

Other observations

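All values here were chosen after they were seen. Of 14132 genes, 183 passed limma's test for any difference between stages and had all 4 early arrays above all other 16 arrays. Another 31 passed it and had them below. Without that test, chance gives 1 in 4845 for each side. The counts for the other stages also hold only genes that passed the test. MELK, a kinase of dividing cells, was at 6.11 ± 0.33 (log2, SD, n = 4) at the early stage and 4.58 ± 0.30 (n = 16) elsewhere, and TRIP13, which acts at the spindle checkpoint, at 6.58 ± 0.32 and 5.23 ± 0.30. The mid stage stood above in 12 genes and below in 16. IL10, an anti-inflammatory cytokine, was at 7.27 ± 0.07 at the mid stage and 6.48 ± 0.36 elsewhere, LYVE1, a receptor of lymphatic vessels and some macrophages, at 9.02 ± 0.09 and 8.11 ± 0.83, and NCKAP1L, an actin regulator of blood cells, at 4.61 ± 0.15 and 5.86 ± 1.15. All 4 mid arrays lay in the low mitochondrial group.

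The mid-late stage stood above in 4 genes and below in 11, among them SERPING1, the inhibitor of complement C1, at 8.39 ± 0.09 against 9.12 ± 0.45. The late stage stood above in 37 and below in 14. FADS2, a fatty acid desaturase, was at 8.56 ± 0.20 at the late stage against 7.56 ± 0.44 elsewhere, and CBR1, a carbonyl reductase, at 7.60 ± 0.22 against 8.20 ± 0.35. The very-late stage stood above in 783 and below in 873. RAC2, a GTPase of blood cells, was at 9.65 ± 0.30 at the very-late stage against 5.34 ± 0.59 elsewhere, TRPV2, a cation channel, at 9.06 ± 0.42 against 5.11 ± 0.38, ID4, an inhibitor of transcription factors, at 6.25 ± 0.86 against 10.54 ± 0.37, and NPTX2, a neuronal pentraxin, at 5.94 ± 0.45 against 10.77 ± 1.04.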
